A study of Coryphaena hippurus with 21 samples.

How the data were processed

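Small RNA was sequenced from whole mahi-mahi (Coryphaena hippurus) larvae at 48 hours post fertilization (hpf). Embryos had developed in clean seawater (control) or in dilutions of a high-energy water-accommodated fraction (HEWAF, oil blended into seawater) of Deepwater Horizon oil. Slick oil was given at 0.5, 1 and 2% (L, M and H) and source oil at 0.125, 0.25 and 0.5% (L, M and H). Each of the 7 groups had 3 libraries, 21 in all. The titles of the source oil samples carry the word mass, and these samples were taken as source oil because the series text names slick and source oil only. RNA came from pooled samples, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate beakers or pools, so each p-value measures the spread between these libraries.

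The authors deposited 1 count table per exposure, each holding whole-number read counts per miRNA name for the 3 exposed libraries and the 3 control libraries. Per the file headers, the names are mature miRNAs, and in 5 of the 6 tables the header adds miRBase. The names carry the prefixes of 47 species, such as ola for medaka and ssa for salmon, and no name belongs to mahi-mahi itself. The aligner, the counting tool and the genome are not given in the sources used here. Each table held 189 to 203 distinct names, 329 names in all with 125 family numbers, and 110 names stood in all 6 tables. The first exposed library of each table had no count of 0, and every other library did. The authors also deposited result tables with group means of scaled counts (a normalized signal), a log2 fold change, a p-value and its adjusted value. The submitters' processing notes name DESeq2 for these tables and give neither a version nor a formula. These result tables list fewer names than the count tables, and their calls are given beside those computed here.

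The control columns held the same counts in all tables, with 0 of 774 shared cells differing. The source H table held 6 blank control cells, and each was filled with the count of the same library and name from another table. A name that stood on more than 1 line of a table (17 extra lines over the 6 tables) was reduced to its highest count per library. The count columns carry numbers that do not follow the replicate numbers of the sample titles, so columns were joined to groups and not to single samples. The library names C4, L5 or M1 used here are those columns. Columns of slick and source oil share letters, and the oil is named each time.

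Counts were tested with edgeR 4.0.16 under R 4.3.3, using TMM library factors, filterByExpr (minimum count 10, minimum total 15), glmQLFit and glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method over all names tested in a comparison, and a name was called when the adjusted value lay under 0.05. The comparisons were each exposure against control within its own table, a slope on the concentration in percent for each oil over 12 libraries, and 4 direct comparisons of the oils. The direct comparisons were slick L with source H, which share the nominal 0.5%, and the L, M and H groups of the oils with each other. Groups of the same letter differ in nominal concentration between the oils. The overlap of slick H and source H was set against 1000 simulations of unchanged exposed groups that share the 3 controls. Levels are given as CPM, scaled counts per library from the cpm function of edgeR after TMM scaling, mean ± SD over the 3 libraries of a group, within the table tested. Log2 fold changes are given with an approximate standard error (SE), computed as the absolute log2 fold change over the square root of the F statistic of the test. The comparisons, tests, lists, alternatives and the rule for naming miRNAs were set before the data were examined, apart from those named here as added.

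Many names held 0 in some libraries beside high counts in others of the same group. Of 1448 zero counts over the tables, 1166 belonged to names that reached at least 100 counts in another library of the table. A further set was therefore added after the data were seen, made of names with a count above 0 in every library of a comparison. These were 113 to 119 names per table before the filter and held 79.6 to 86.1% of the reads. Both counts of calls are given throughout, with the fixed design first. A call whose control libraries are all at 0 has no finite fold, and a lower bound against a floor of 3 counts over the 3 control libraries is given instead. Each table lists only names found in its first exposed library, so such a call can only be higher. Reads of a family given to different names in different libraries could produce it, so it may not stand for a rise of the miRNA. Names of near-identical sequence can share reads, so a single name of a family may not stand for a single miRNA.

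The miRNAs named in the text follow 1 rule. Among names called in a comparison whose 3 libraries of one group all lay above the 3 of the other, up to 12 higher and 12 lower with the largest log2 fold change were taken for slick H and source H, and up to 6 and 6 elsewhere. In comparisons with fewer than 4 such names, the 4 with the smallest p were taken. The rule added 2 to 4 members with the smallest p from each list, the 5 miRNAs with the highest mean CPM, and those called the same way in at least 4 of the 6 exposures. Names that fall outside it were chosen after their values were seen and are marked so.

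The 15 lists came from general knowledge of where vertebrate miRNAs are expressed, with members matched by family number. They were miRNAs of muscle and heart, neurons, eye and sensory organs, blood cells, endothelium and smooth muscle, epithelia, liver, gut and pancreas, and cartilage and connective tissue. The others were the let-7, miR-430, miR-181 and miR-30 families, the miR-17-92 clusters, the p53, hypoxia and stress-linked miRNAs, and the Hox cluster miRNAs. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives.

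Alternatives were RLE size factors, total counts without a composition factor, no filter on low counts, DESeq2 1.42.0, 1 fit over all 21 libraries, a minimum absolute log2 fold change of 1, dose as a rank, exposed groups only in the trends, and leaving out each library in turn. A block on the replicate number was planned and not run. Alternatives added after the data were seen were the names counted in every library, names of 1 family merged where their counts lay within 2% of each other, and fits of the names counted in every library without single libraries. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

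The steps were tested on simulated data with 20 names raised or lowered 2-fold and 20 changed 4-fold in each of 20 runs. For slick H vs control over 155 to 158 names, edgeR recovered 35% of the 2-fold and 85.9% of the 4-fold changes, and 4.75% of its calls were unchanged names. Over 110 to 113 names counted in every library these shares were 65.6%, 98.7% and 4.53%. For source H vs control over 156 to 160 names they were 14.3%, 69.5% and 15.7%, and over 109 to 110 names counted in every library 49.5%, 96.7% and 4.43%. For the slick dose trend over 126 to 127 names they were 54.8%, 96% and 2.75%. The simulated libraries kept the zeros of the real ones, and only names without a zero were changed. The recovered shares therefore do not cover names with zeros. A name at 0 in all controls kept that difference and counted as unchanged when called. The shares of unchanged names over all names, such as 15.7%, can include such names. Camera called the miR-17-92 clusters in 20 of 20 runs when their 10 members were raised 2-fold among 113 names, and called 0 other lists.

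Total counts per library ranged from 3157670 to 8736995 in the exposed libraries and from 6105389 to 7897029 in the controls over the tables. The 3-count floor covers counting error only, since reads without molecular identifiers are not independent molecules. No paired fit, target prediction or genome comparison was made, because the files pair no libraries and no reference was used.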

Results

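MicroRNA counts were obtained from 21 libraries of whole mahi-mahi larvae at 48 hpf, 3 for each of 7 groups. The groups were control seawater, slick oil at 0.5% (L), 1% (M) and 2% (H), and source oil at 0.125% (L), 0.25% (M) and 0.5% (H). Slick oil is oil that had weathered at the sea surface, and source oil is the oil as it left the well. The libraries held 7692673 to 8736995 counts in slick L, 6230239 to 7636400 in slick M, 3407490 to 8284057 in slick H, 5051272 to 7378740 in source L, 3641165 to 7198086 in source M and 3157670 to 8660114 in source H. The control libraries held 6105389 to 7897029 counts over the 6 tables.

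A small number of miRNAs made up most of the counts. The name ssa-miR-206-5p, of a family made in skeletal muscle, took 37.4% of all counts, with a mean of 399790 CPM over the 21 libraries. The neural family name aca-miR-9-5p followed with 30% and 292950 CPM. In the 3 control libraries the order was the reverse, with aca-miR-9-5p at 390530 ± 48987 and ssa-miR-206-5p at 300020 ± 81852 CPM (scaled over the 99 names counted in all 21 libraries). Next came ola-miR-21 with 5.87%, cgr-miR-26a with 3.34% and sha-miR-181a-5p with 2.46%. The last 2 of these names held 0 in at least 1 library each.

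Over the 99 names counted in all 21 libraries, the first principal component held 51.1% of the variance and set 7 libraries apart from the other 14. These were the 3 source M libraries, the 3 source H libraries and library L3 of source L, and the lowest of the 7 lay at 5.01 against at most -2.06 for the others. Libraries L1 and L2 of source L lay with the control and slick libraries. The values of source M and source H below therefore all come from this set of 7 libraries.

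**Figure D1:**
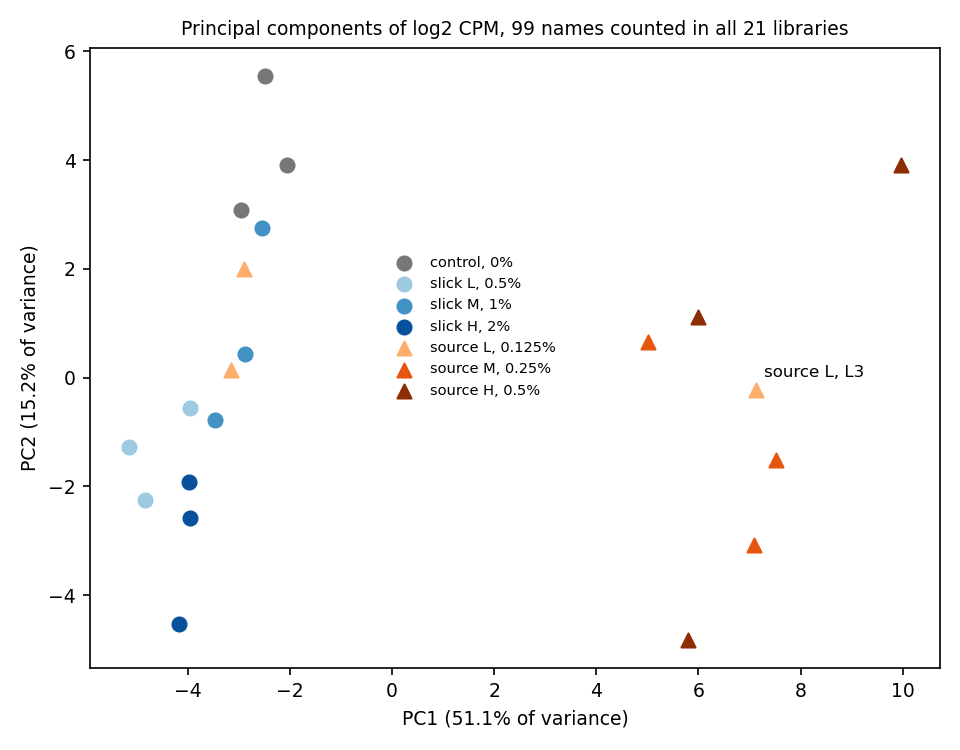
Each point is a library, placed by its scores on the first component (51.1% of variance, horizontal axis) and the second (15.2%, vertical axis) of log2 CPM over 99 names. Colour gives group and dose, and triangles are source oil. The 3 source M, the 3 source H and 1 source L library (L3) lie at 5.01 or above on the first component, and the other 14 lie at -2.06 or below.

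The comparison of slick L with control asked which miRNAs respond to the lowest slick dose. In slick L larvae the miR-23 and miR-126 names, of families known from endothelium, were higher. The name oar-miR-23b rose from 153 ± 30.4 to 536 ± 23.0 CPM (log2 fold change 1.81 ± 0.18 SE, adjusted p = 0.00554), and tgu-miR-126-5p from 5928 ± 575 to 20567 ± 8446 CPM (1.79 ± 0.39, adjusted p = 0.0452). The teleost miRNA ola-miR-462 (2.02 ± 0.30), the neuronal aca-miR-132-5p (1.88 ± 0.26) and sha-miR-92a of the miR-17-92 clusters (1.42 ± 0.15) rose as well. Lower were ggo-miR-499a, which lies in a myosin gene in vertebrates, from 1471 ± 123 to 584 ± 46.2 CPM (-1.33 ± 0.13, adjusted p = 0.00554), and the red blood cell miRNA ssa-miR-144-3p, from 377 ± 45.8 to 188 ± 36.3 CPM (-1.0 ± 0.18, adjusted p = 0.0287). The names ola-miR-214 (-1.27 ± 0.25) and ola-miR-101b-3p (-1.11 ± 0.15) also fell.

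In slick L 23 of 159 names were called, 13 higher and 10 lower, and in all 23 the 3 exposed libraries lay on one side of the 3 controls. Such separation was found for 68 names (42.8%), where chance gives 10%. Among the 114 names counted in every library 44 were called, 20 higher and 24 lower, including 21 of the 23. The authors' deposited table called 44 names in this exposure, 41 of them among these 44 and 0 in the opposite direction. Among the other 2 of the 23, gga-miR-30e-5p was at least 70364-fold and aca-miR-125a-5p at least 5760-fold above controls that all stood at 0. In the same libraries ola-miR-30a-5p of the same family fell by 8.16 on the log2 scale, and the sum of all miR-30 names was 10646 ± 1383 CPM in control and 17491 ± 1987 CPM in slick L. The count was 11 without control C4, 14 without C5, 9 without C6, 10 without slick L library L5 and 9 without L6, and among names counted in every library it was 25 without L5.

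Of the endothelial and smooth muscle list in slick L, 4 of 13 members rose and 0 fell, namely 2 names of miR-23b, dre-miR-23a-3-5p (1.44 ± 0.17) and tgu-miR-126-5p. Of 7 blood cell miRNAs 1 rose (ola-miR-462) and 1 fell (ssa-miR-144-3p), and 1 rose and 3 fell when adjusted over the list alone. This list holds ola-miR-142 and tgu-miR-142-5p, which have the same counts. Of 7 cartilage and connective tissue miRNAs 2 fell, both names of miR-214, and 2 fell adjusted over the list alone. Of 6 muscle and heart miRNAs 1 fell, of 20 neuronal miRNAs 1 rose and 1 fell, and of 10 members of the miR-17-92 clusters 1 rose, with the same counts adjusted over the list alone. In the miR-181 family 1 of 5 rose and 1 fell (2 and 1 adjusted over the list alone), and in the miR-30 family 1 of 6 rose and 1 fell. The miR-30 name that rose was gga-miR-30e-5p, at 0 in all controls. No member passed in the eye and sensory organ (4), epithelial (4), liver, gut and pancreas (7), let-7 (8), miR-430 (3), p53, hypoxia and stress-linked (6) and Hox cluster (5) lists, over all names or over the list alone. Camera called 0 of 15 lists, with a lowest adjusted p = 0.267 for cartilage and connective tissue and 0.972 with an estimated correlation. Median, mean and test differed in sign for the muscle and heart list and the liver, gut and pancreas list. Among names counted in every library camera also called 0 lists, and 3 of 5 p53, hypoxia and stress-linked miRNAs rose, namely aca-miR-34b-5p (1.04), ipu-miR-107b (0.92) and oar-miR-16b (0.65). In that set the muscle name rno-miR-133b-5p rose (0.90 ± 0.29) while ggo-miR-499a fell, and 1 member each fell in the epithelial, the liver, gut and pancreas, and the let-7 lists.

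The middle slick dose was compared with control in the same way. The endothelial family name oar-miR-23b stood at 164 ± 23.4 CPM in control and 405 ± 89.1 CPM in slick M. Its log2 fold change of 1.30 ± 0.24 missed the threshold over all names (adjusted p = 0.114) and passed it among names counted in every library (adjusted p = 0.0204). In that set dre-miR-23a-3-5p (1.05 ± 0.25) and oan-miR-458-5p (1.05 ± 0.25) rose as well, while ssa-miR-23b-5p, at 1.0 ± 0.29, missed the threshold (adjusted p = 0.0643). The neuronal family names mdo-miR-128a-5p (-1.14 ± 0.28) and oha-miR-9-4-5p (-1.28 ± 0.33) fell. The far more abundant aca-miR-9-5p, of the same family number as oha-miR-9-4-5p, stood at -0.11 and was not called.

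Over all 159 names only ipu-miR-203b and xtr-miR-129 were called in slick M, both higher, and both stood at 0 in all controls. They lay at least 270550-fold and at least 11663-fold above the floor. Such calls can only be higher, because a table lists only names found in its first exposed library. Reads of a family given to different names in different libraries could produce them, and no sum over either family was taken. DESeq2 called 24 names and 17 had an unadjusted p under 0.05, and 30 names (18.9%) had groups that did not overlap, where chance gives 10%. Of the 112 names counted in every library 5 were called, 3 higher and 2 lower, with no name shared with the first set, and the authors' deposited table called 12 that include these 5. The count was 8 without slick M library M4, 0 without M5 and 4 without M6, and among names counted in every library it was 32 without M5, 2 without C6 and 0 without C4, C5, M4 or M6. The median SD of log2 CPM over names was 0.346 in slick M, 0.225 in slick L, 0.284 in slick H and 0.234 in control.

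Of the lists in slick M, 1 of 5 epithelial members (ipu-miR-203b) and 1 of 21 neuronal members (xtr-miR-129) were called higher, with the same counts adjusted over the list alone. Both stood at 0 in all controls, where reads may have gone to another name of the family, so neither call shows that the family rose. Adjusted over the list alone, 2 of 14 endothelial and smooth muscle miRNAs and 2 of 5 miR-181 names rose, against 0 over all names. The other lists had no member that passed, over all names or over the list alone. Camera called 0 of 14 lists, with a lowest adjusted p = 0.314 for blood cell miRNAs and 0.863 with an estimated correlation. Median, mean and test differed in sign for muscle and heart, neuronal, liver, gut and pancreas, cartilage and connective tissue, and miR-430.

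At the highest slick dose oar-miR-23b rose from 152 ± 31.7 to 649 ± 62.6 CPM (2.09 ± 0.22, adjusted p = 0.0115), tgu-miR-126-5p from 5879.5 ± 831 to 18330 ± 3739 CPM (1.64 ± 0.23, adjusted p = 0.0148) and ola-miR-462 from 341 ± 50 to 1010 ± 120 CPM (1.57 ± 0.18, adjusted p = 0.0117). The names aca-miR-132-5p (1.98 ± 0.33), ssa-miR-734-5p (1.51 ± 0.15), sha-miR-92a (1.26 ± 0.20) and ssa-miR-181b-5p (1.19 ± 0.23) rose as well. The muscle miRNA ggo-miR-499a fell from 1452 ± 75.0 to 510 ± 169 CPM (-1.51 ± 0.30, adjusted p = 0.0427), and ssa-miR-144-3p from 372 ± 37.8 to 152 ± 18.1 CPM (-1.29 ± 0.16, adjusted p = 0.0124). The names dre-miR-301c-5p (-1.38 ± 0.23), ssa-miR-301a-5p (-0.92 ± 0.12), aca-miR-26-5p (-0.90 ± 0.18) and hsa-miR-181b-2-3p (-0.86 ± 0.16) fell.

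In slick H 16 of 158 names were called, 10 higher and 6 lower, all with groups that did not overlap, as was the case for 57 names (36.1%) where chance gives 10%. One of them, tni-miR-216a, stood at 0 in all controls and lay at least 431-fold above the floor. Among the 113 names counted in every library 31 were called, 15 higher and 16 lower, including 15 of the 16. These added ssa-miR-137-5p (1.54), rno-miR-133b-5p (1.40), aca-miR-34b-5p (1.31) and ipu-miR-107b (1.25) to those that rose, and oan-miR-145-5p (-1.20) and mdo-miR-128a-5p (-1.23) to those that fell. The authors' deposited table called 39 names, all 31 among them. In that set slick L and slick H shared 14 names that rose and 13 that fell, and 0 went in opposite directions. Both were set against the same 3 controls, and shared controls were not simulated for this pair. The count was 8 without control C4, 1 without C5, 1 without C6 and 8 without slick H library H6, and among names counted in every library it was 19 without C6.

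Of 16 endothelial and smooth muscle miRNAs in slick H 4 rose, the same 4 names as in slick L, and 4 rose and 1 fell adjusted over the list alone. Of 7 blood cell miRNAs 1 rose and 1 fell, and 1 rose and 4 fell adjusted over the list alone. Among names counted in every library 1 of 7 rose and 4 fell, including ola-miR-731 (-0.89) and 2 miR-142 names with the same counts (ola-miR-142, -0.85). Of 6 muscle and heart miRNAs 1 fell, and of 10 members of the miR-17-92 clusters 1 rose, as over the list alone. In the set counted in every library 1 of 3 muscle and heart names rose (rno-miR-133b-5p) and 1 fell. Of 21 neuronal miRNAs 1 rose (2 rose and 2 fell adjusted over the list alone), of 5 liver, gut and pancreas miRNAs 1 rose (2 over the list alone), and of 5 miR-181 names 1 rose and 1 fell (2 and 1 over the list alone). The liver, gut and pancreas name called over all names was tni-miR-216a, at 0 in all controls. Reads there may have gone to another name of the family, so that call does not show a rise. Of 4 epithelial miRNAs 0 changed over all names and 1 fell over the list alone, and the other lists had no member that passed. Camera called 0 of 14 lists, with a lowest adjusted p = 0.264 for the miR-17-92 clusters and 0.958 with an estimated correlation. Median, mean and test differed in sign for muscle and heart, cartilage and connective tissue, let-7, miR-430 and miR-181.

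The lowest source dose gave no call over all names. The 4 names with the smallest p were ssa-miR-727-3p, at 0 in all controls and 91.0 ± 63.1 CPM in source L, ola-miR-101b-3p (-1.36 ± 0.31), ola-miR-148 (-1.06 ± 0.25) and ssa-miR-206-5p (0.99 ± 0.24), with adjusted p = 0.236 to 0.256. The muscle miRNA ssa-miR-206-5p stood at 212420 ± 50598 CPM in control and 423080 ± 64351 CPM in source L. Among names counted in every library oar-miR-23b was at 1.16 ± 0.28 (adjusted p = 0.117).

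In source L edgeR called 0 of 152 names and 24 had an unadjusted p under 0.05, while DESeq2 called 32. Among the 110 names counted in every library edgeR called 0, with 25 at an unadjusted p under 0.05, and the authors' deposited table called 24. The groups did not overlap for 44 of the 152 names (28.9%), where chance gives 10%. Without library L3, which lay with source M and source H, 27 of the names counted in every library were called, 11 higher and 16 lower, and the count over all names was 2 without control C5, 2 without L1 and 0 without L3. Scaling by total counts moved the median log2 fold change by -0.28 in this comparison, and it still gave 0 calls. No member of any list passed over all names or over the list alone, and camera called 0 of 14 lists, with a lowest adjusted p = 0.30 for cartilage and connective tissue and 0.929 with an estimated correlation. Median, mean and test differed in sign for eye and sensory organ miRNAs and for miR-30.

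At the middle source dose 2 let-7 and 2 miR-196 names fell and 3 miR-181 names rose. The name ola-let-7g, of a family that times development, fell from 1381 ± 55.6 to 158 ± 39.0 CPM (-3.12 ± 0.24, adjusted p = 0.00313), and hhi-miR-196, which is encoded in the Hox clusters, fell from 1354 ± 231 to 348 ± 19.7 CPM (-1.96 ± 0.18, adjusted p = 0.00447). Lower too were tgu-miR-126-5p, from 5784 ± 457 to 2006 ± 195 CPM (-1.53 ± 0.15, adjusted p = 0.00447), and sha-miR-92a, from 8632 ± 848 to 1758 ± 947 CPM (-2.30 ± 0.43, adjusted p = 0.0196). Both had risen in slick L and slick H. The names ccr-miR-454b (-2.27 ± 0.57), ipu-miR-130c (-2.04 ± 0.23) and dre-miR-301c-5p (-1.81 ± 0.21) fell as well. Among those that rose were ssa-miR-137-5p (1.74 ± 0.35), dre-miR-93 (1.55 ± 0.27), cfa-miR-181b (1.53 ± 0.22) and ola-miR-19b (1.5 ± 0.24). The more abundant let-7 name mse-let-7a lay the other way among names counted in every library. It stood at 4255 ± 557 CPM in control and 11206 ± 6135 CPM in source M, with groups that overlapped. No sum over the let-7 names was taken, so the fall of ola-let-7g does not show that the family fell.

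In source M 36 of 150 names were called, 16 higher and 20 lower, all with groups that did not overlap, as was the case for 81 names (54.0%) where chance gives 10%. Of the 16 that rose, 3 stood at 0 in all controls, namely ipu-miR-203b, gga-miR-30e-5p and dre-miR-139-5p, at least 176780-fold, 19552-fold and 175-fold above the floor. As in slick L, ola-miR-30a-5p of the same family as gga-miR-30e-5p lay the other way (-8.21, adjusted p = 0.142), and no sum over the family was taken here. Among the 108 names counted in every library 61 were called, 30 higher and 31 lower, including 33 of the 36. The authors' deposited table called 58 names, 56 of them in that set. The 3 source M libraries all belonged to the set of 7 that stood apart on the first component. The count was 14 without control C4, 20 without C5 and 11 without C6, it was 7 with total counts as scaling (which moved the median by -0.22), and among names counted in every library it was 40 without C4 and 40 without source M library M3.

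Of 10 members of the miR-17-92 clusters in source M 3 rose (2 names of miR-19 and dre-miR-93) and 3 fell (sha-miR-92a, oan-miR-20a-5p and ssa-miR-18a-5p), as over the list alone. Of 5 miR-181 names 3 rose and 0 fell, of 6 Hox cluster miRNAs 2 fell, both names of miR-196, and of 8 let-7 names 2 fell, ola-let-7g and ola-let-7e (-1.31 ± 0.33), each as over the list alone. Of 7 blood cell miRNAs 2 fell, ola-miR-462 (-0.75 ± 0.15) and tgu-miR-155-5p (-1.58 ± 0.24), and of 14 endothelial and smooth muscle miRNAs 1 fell, as over the list alone. Of 22 neuronal miRNAs 2 rose, of 4 muscle and heart miRNAs 1 fell, and of 5 epithelial and 5 miR-30 names 1 each rose, as over the list alone. The epithelial and miR-30 names were ipu-miR-203b and gga-miR-30e-5p, both at 0 in all controls. Reads there may have gone to another name of the family, so neither call shows that the family rose. Of 5 liver, gut and pancreas miRNAs 1 rose over all names, and 1 rose and 2 fell over the list alone. The eye and sensory organ, cartilage and connective tissue, miR-430, and p53, hypoxia and stress-linked lists had no member that passed. Camera called 0 of 14 lists, with a lowest adjusted p = 0.759 for neuronal miRNAs and 0.905 with an estimated correlation. Median, mean and test differed in sign for muscle and heart, eye and sensory organ, blood cell, liver, gut and pancreas, cartilage and connective tissue, let-7 and miR-30. Among names counted in every library 6 of 13 neuronal miRNAs rose and 3 fell, with ola-miR-124-5p (1.26) and ssa-miR-137-5p (1.70) among the first and ola-miR-135a (-1.38) among the second. The 6 include ola-miR-124-5p and dre-miR-124-4-5p, whose exposed libraries hold the same counts. In that set 2 of 6 blood cell miRNAs rose, both names of miR-142 with the same counts (ola-miR-142, 0.87 ± 0.26), and 2 fell. Of 12 endothelial and smooth muscle miRNAs 5 rose, 3 of them miR-24 names with the same counts, and 3 fell. Of 4 let-7 names there 1 rose (mse-let-7a, 1.4 ± 0.45, with groups that overlapped) and 2 fell.

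At the highest source dose ola-let-7g fell from 1227 ± 78.0 to 141 ± 63.9 CPM (-3.13 ± 0.44, adjusted p = 0.0236), ccr-miR-454b from 601 ± 117 to 78.6 ± 33.3 CPM (-2.94 ± 0.44, adjusted p = 0.0236) and ola-miR-130c from 153 ± 44.6 to 39.0 ± 1.88 CPM (-1.97 ± 0.29, adjusted p = 0.0236). The name ola-miR-187 rose from 313 ± 57.0 to 831 ± 88.5 CPM (1.41 ± 0.23, adjusted p = 0.0296) and ola-miR-181a-5p from 13670 ± 1062 to 36712 ± 8603 CPM (1.43 ± 0.24, adjusted p = 0.0296). The names aca-miR-727-5p (1.54 ± 0.26) and tgu-miR-217-5p (1.32 ± 0.26), the latter known from pancreas, rose as well. Lower were also oha-miR-9-4-5p (-2.28 ± 0.42), dre-miR-737-5p (-1.93 ± 0.33), ipu-miR-130c (-1.76 ± 0.23) and ola-miR-135a (-1.45 ± 0.25). The far more abundant aca-miR-9-5p stood at -0.38 among names counted in every library. In that set the let-7 name mse-let-7a rose (1.73), so the fall of ola-let-7g does not show that the let-7 family fell.

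In source H 15 of 160 names were called, 8 higher and 7 lower, all with groups that did not overlap, as was the case for 80 names (50%) where chance gives 10%. The names gga-miR-30e-5p, rno-miR-129-5p and ccr-miR-196b stood at 0 in all controls and lay at least 28394-fold, 62533-fold and 622-fold above the floor. No sum over their families was taken. Among the 110 names counted in every library 55 were called, 30 higher and 25 lower, including 12 of the 15, and the authors' deposited table called 58, of which 53 were in that set. These added ssa-miR-206-5p (1.32 ± 0.19), 2 near-identical let-7 names (mse-let-7a, 1.73 ± 0.36) and aca-miR-34b-5p (2.41 ± 0.63) to those that rose, and sha-miR-92a (-1.72 ± 0.36), oan-miR-20a-5p (-1.83 ± 0.42) and tgu-miR-155-5p (-1.61 ± 0.49) to those that fell. Source M and source H shared 23 names that rose and 21 that fell in that set, against the same 3 controls, and all 6 libraries belonged to the 7 that stood apart on the first component. With total counts as scaling, which moved the median by -0.42, 6 names were called higher and 24 lower (20% higher against 53.3%), and with RLE factors, which moved it by -0.13, 13 were called higher and 16 lower. The count was 5 without control C4, 2 without C5, 3 without C6, 24 without source H library H1, 0 without H2 and 36 without H3, and among names counted in every library it was 30 without C4, 34 without C5 and 12 without C6.

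Of 5 miR-181 names in source H 2 rose and 0 fell, and 4 rose adjusted over the list alone. Of 8 let-7 names 1 fell (2 rose and 2 fell over the list alone), and of 6 Hox cluster miRNAs 1 rose (1 rose and 1 fell over the list alone). Of 21 neuronal miRNAs 1 rose and 2 fell, of 5 miR-30 names 1 rose, and of 4 liver, gut and pancreas miRNAs 1 rose (1 rose and 1 fell over the list alone). The Hox cluster, neuronal and miR-30 names called higher over all names were ccr-miR-196b, rno-miR-129-5p and gga-miR-30e-5p. These names stood at 0 in all controls, where reads may have gone to another name of the family. Their calls thus do not show that the families rose. The next lists had 0 calls over all names. Adjusted over the list alone, 3 of 15 endothelial and smooth muscle miRNAs (miR-24 names with the same counts) rose and 1 fell, 3 of 7 cartilage and connective tissue miRNAs fell, 2 of 10 members of the miR-17-92 clusters rose and 2 fell, and 1 of 5 muscle and heart miRNAs rose. The eye and sensory organ, blood cell, epithelial, miR-430, and p53, hypoxia and stress-linked lists had no member that passed. Among names counted in every library 3 of 5 let-7 names rose and 2 fell, 3 of 10 members of the miR-17-92 clusters rose and 2 fell, 2 of 4 Hox cluster names fell (both miR-196), and 1 of 6 blood cell miRNAs rose (ola-miR-731, 0.80 ± 0.23) and 1 fell. Camera called 0 of 15 lists, with a lowest adjusted p = 0.723 for miR-181 and 0.959 with an estimated correlation. Median, mean and test differed in sign for muscle and heart, blood cell, epithelial, miR-430, and p53, hypoxia and stress-linked miRNAs.

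**Figure D2:**
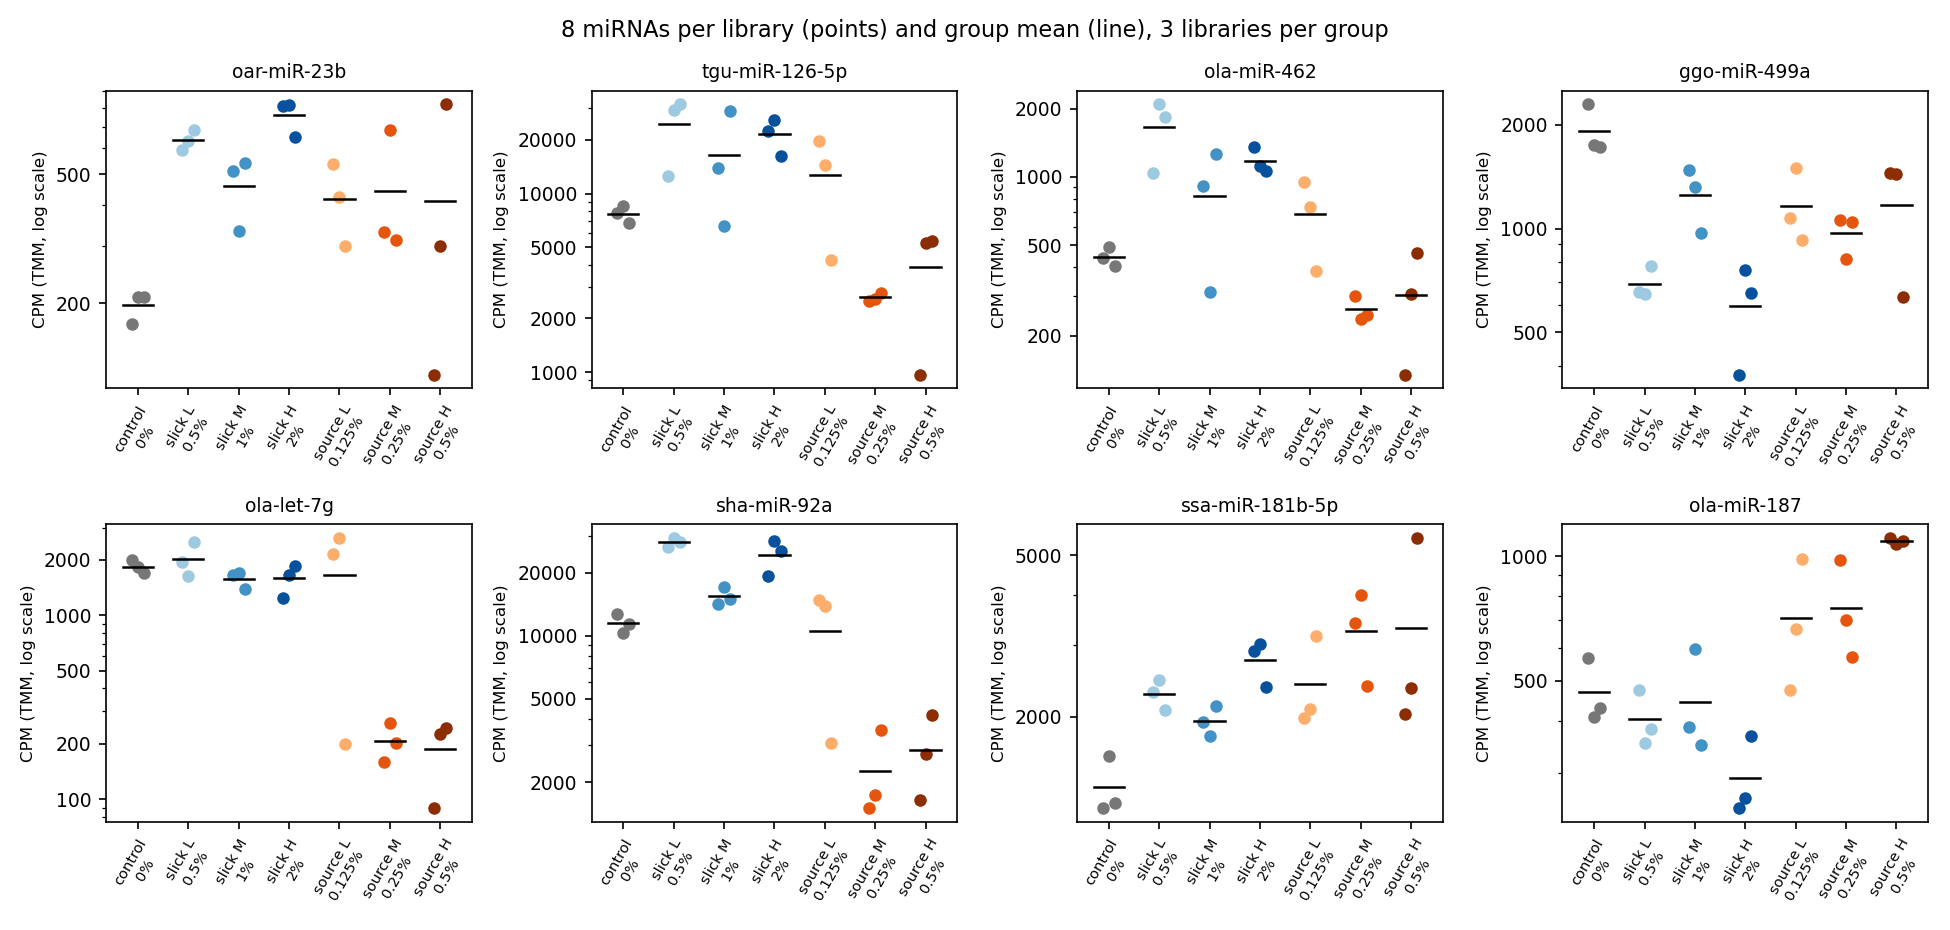
Each panel gives the CPM (TMM-scaled, log axis) of 1 miRNA in 21 libraries, with points for libraries, lines for the group mean of 3, and groups by oil and dose on the horizontal axis. In slick L and slick H oar-miR-23b, tgu-miR-126-5p, ola-miR-462 and sha-miR-92a lie above the 3 controls and ggo-miR-499a lies below, and in source M and source H ola-let-7g and sha-miR-92a lie below. In source L, 1 of 3 points of ola-let-7g lies with source M and source H.

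The series title speaks of dose response, so the slope on concentration was tested for each oil. For slick oil ssa-miR-734-5p rose with dose, from 1415 ± 20 CPM in control over 2496 ± 391 and 2417 ± 662 to 3880 ± 341 CPM in slick H (log2 change from 0 to the highest dose 1.28 ± 0.24, adjusted p = 0.0280). The neuronal miRNA ssa-miR-137-5p (1.63 ± 0.37) and ssa-miR-181b-5p (0.93 ± 0.24) rose too. The slope was negative for dre-miR-301c-5p (-1.33 ± 0.31), ssa-miR-144-3p (-1.16 ± 0.26), ola-miR-731 (-1.01 ± 0.24) and ssa-miR-301a-5p (-0.85 ± 0.22).

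In the slick dose trend 7 of 128 names were called, 3 higher and 4 lower, and 13 of the 106 names counted in every library, 7 higher and 6 lower. The latter added oar-miR-23b (1.49), efu-miR-29b (1.45) and dre-miR-23a-3-5p (1.23) to those that rose and ggo-miR-499a (-1.29) and mdo-miR-128a-5p (-1.14) to those that fell. With the control libraries left out, edgeR called 0 names over the 3 doses. The count was 0 without C4, C5, C6 or slick H library H4 or H5, 3 without H6, 2 without slick M library M4 and 11 without slick L library L5, and with total counts as scaling 2 names were called higher and 5 lower (28.6% higher against 42.9%).

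For source oil the slope was negative for most called names. From control to source H the group means of ola-let-7g were 1477 ± 65.3, 1271 ± 965, 158 ± 35.1 and 138 ± 64.8 CPM (-3.79 ± 0.91, adjusted p = 0.0197). Those of ccr-miR-454b were 726 ± 154, 393 ± 303, 148 ± 121 and 76.9 ± 33.9 CPM (-3.28 ± 0.74, adjusted p = 0.0197). The names sha-miR-92a (-2.36 ± 0.72), tgu-miR-155-5p (-2.35 ± 0.68), ola-let-7e (-2.31) and ola-miR-130c (-2.29) fell as well. The let-7 name mse-let-7a, more abundant than ola-let-7g, rose in source H against control (1.73 ± 0.36 among names counted in every library). Over all names past the filter, with TMM scaling, the only call with a positive slope was ola-miR-187 (0.99 ± 0.27, adjusted p = 0.0294). In source L against control, over names counted in every library, ola-let-7g stood at 1848.6 and 2042.5 CPM in L1 and L2. It stood at 175.17 CPM in L3 and 1393.4 to 1497.3 CPM in control. Its source L mean was thus no intermediate level. L3 and all source M and source H libraries belonged to the set apart on the first component. The trend cannot tell a slope from a step at that set or a batch shared by it.

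In the source dose trend 20 of 121 names were called, 1 higher and 19 lower, and 25 of the 105 names counted in every library, 3 higher and 22 lower. Without library L3 of source L, which lay with the higher doses, 38 of the names counted in every library were called, and with the control libraries left out edgeR called 0 names over the 3 doses. The count over all names was 8 without C4, 1 without C5, 0 without C6, source L library L1 or L2, 9 without source M library M1, and 6, 13 and 12 without source H libraries H1, H2 and H3. RLE factors moved the median by 0.18 and gave 2 higher and 14 lower (12.5% higher against 5.0%), and with total counts as scaling 2 names were called higher and 10 lower (16.7% higher).

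Slick L and source H share the nominal 0.5% dilution, and their direct comparison asked how the oils differ at the same dilution. Higher in slick L were ola-let-7g, at 1702 ± 266 CPM against 151 ± 78.5 in source H (3.49 ± 0.51, adjusted p = 0.0197), ccr-miR-454b (3.39 ± 0.48) and sha-miR-92a, at 23733 ± 2687 against 2354 ± 1336 CPM (3.33 ± 0.48, adjusted p = 0.0197). The names oan-miR-20a-5p (2.51 ± 0.51), ola-miR-130c (2.31 ± 0.28) and ipu-miR-130c (1.88 ± 0.27) were higher too. Lower in slick L were dre-miR-22a-5p (-1.72 ± 0.20, adjusted p = 0.0197), ssa-miR-7132b-5p (-1.46 ± 0.23), ola-miR-187 (-1.36 ± 0.23), aca-miR-727-5p (-1.33 ± 0.30) and sha-miR-181a-5p (-1.25 ± 0.26).

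Here 16 of 139 names were called, 9 higher and 7 lower in slick L, and 45 of the 111 names counted in every library, 24 higher and 21 lower. The latter added tgu-miR-126-5p (2.72 ± 0.60) and ola-miR-462 (2.52 ± 0.49) among those higher in slick L. Groups did not overlap for 69 names (49.6%), where chance gives 10%, and all 3 source H libraries belonged to the 7 that stood apart on the first component. With total counts as scaling, which moved the median by 0.32, 26 names were higher and 6 lower (81.2% higher against 56.2%), and with RLE factors, which moved it by -0.11, 12 were higher and 16 lower (42.9%). The count was 1 without source H library H2, 39 without H3, 9 without slick L library L4 and 0 without L5 or L6.

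Slick L and source L, the lowest dose of each oil, showed no call. The 4 names with the smallest p were ggo-miR-499a (-0.74 ± 0.19), rno-miR-133b-5p (1.13 ± 0.29), ssa-miR-206-5p (-0.85 ± 0.22) and dre-miR-153b-5p (-0.69 ± 0.18), each with adjusted p = 0.316. Of these ssa-miR-206-5p stood at 268320 ± 49858 CPM in slick L and 482210 ± 97025 CPM in source L. Of 132 names edgeR called 0, 15 had an unadjusted p under 0.05 and DESeq2 called 17, and of the 111 names counted in every library edgeR called 0, with 20 at an unadjusted p under 0.05. The groups did not overlap for 33 names (25.0%), where chance gives 10%, total counts as scaling moved the median by 0.46, and the count was 1 without source L library L1 and 1 without slick L library L4.

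Between slick M and source M, ola-let-7g stood at 1284 ± 127 against 176 ± 40.4 CPM (2.86 ± 0.25, adjusted p = 0.00741) and sha-miR-92a at 12612 ± 1291 against 1953 ± 1017 CPM (2.69 ± 0.43, adjusted p = 0.0303), both higher in slick M. The names ipu-miR-130c (1.86), oan-miR-20a-5p (1.83) and hhi-miR-196 (1.53 ± 0.20) were higher as well. Lower in slick M were ola-miR-19b, at 261 ± 59.7 against 877 ± 213 CPM (-1.75 ± 0.28, adjusted p = 0.0303), sma-miR-124b-5p (-1.61), the blood cell miRNA ola-miR-142 (-1.42 ± 0.26) and tgu-miR-217-5p (-1.13). In all 14 of 127 names were called, 7 higher and 7 lower, and 41 of the 104 names counted in every library, 25 higher and 16 lower. Groups did not overlap for 54 names (42.5%), where chance gives 10%. The count was 6 without source M library M1, 1 without M3, 5 without slick M library M5, 0 without slick M library M4 or M6, and 0 with total counts as scaling, which moved the median by 0.39. Slick M was at 1% and source M at 0.25%, so oil and concentration cannot be told apart here.

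At the highest dose of each oil ccr-miR-454b stood at 995 ± 167 CPM in slick H and 84.7 ± 32.3 in source H (3.56 ± 0.41, adjusted p = 0.0183), and ola-let-7g at 1291 ± 282 and 151 ± 62.7 CPM (3.09 ± 0.44, adjusted p = 0.0183). The names sha-miR-92a (3.08 ± 0.41) and oan-miR-20a-5p (2.83) were higher in slick H too. Lower in slick H were ola-miR-187, at 237 ± 60.6 against 909 ± 107 CPM (-1.94 ± 0.27, adjusted p = 0.0183), mmu-miR-466i-5p (-2.57), ssa-miR-7132b-5p (-1.85 ± 0.29), aca-miR-727-5p (-1.64 ± 0.25) and ola-miR-731 (-1.56 ± 0.31). In all 18 of 138 names were called, 10 higher and 8 lower, and 43 of the 111 names counted in every library, 19 higher and 24 lower. Groups did not overlap for 63 names (45.7%), where chance gives 10%, and total counts as scaling moved the median by 0.43 and gave 17 higher and 5 lower (77.3% higher against 55.6%). The count was 0 without source H library H2, 30 without H3, and 0 without slick H library H5 or H6.

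The overlap of slick H and source H asked how far the oils share changes at their highest doses. Of 132 names tested in both, edgeR called 0 in the same direction in both exposures (0.303 and 0.318 for higher and lower by independent draws), although 8 and 5 were higher and 6 and 7 lower, and DESeq2 called 15 the same way. Of 108 names counted in all 9 libraries 4 were higher in both (3.49 by independent draws) and 5 lower in both (3.70 by independent draws), and 3 went in opposite directions. The correlation of the log2 fold changes across these names was 0.239 (Pearson) and 0.289 (Spearman), where 1000 simulations of unchanged groups with the same 3 controls gave medians of 0.493 (0.276 to 0.676) and 0.473 (0.302 to 0.627), and both lay below the simulated range. The simulated groups hold no changes, and changes found in 1 oil only would lower a correlation. A value below the range therefore does not show that the oils share less than unchanged groups. The covariance of 0.217 lay above its simulated range (median 0.0794, 0.0388 to 0.139). The share of names with the same sign, 58.3%, lay inside its range (median 66.1%, 56.5 to 75.9%). The 9 names called the same way compare with a simulated median of 0 (0 to 0). Groups without changes yield few calls, so this count does not show sharing beyond the independent draws. Names are not independent replicates, and the 3 controls are too few to be split between the exposures.

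Across the 6 exposures 89 of the names counted in every library were called against control at least once, and 9 were called in the same direction in at least 4. All 6 comparisons used the same 3 controls, so these calls are not independent, and shared controls were not simulated over the 6 exposures. The names oar-miR-23b and dre-miR-23a-3-5p share a family number and had similar CPM, so they may not be separate cases. Higher were oar-miR-23b, dre-miR-23a-3-5p, aca-miR-34b-5p, of a family induced by p53, ssa-miR-181b-5p and ssa-miR-734-5p, with oar-miR-23b between 1.16 in source L, where it was not called, and 2.03 in slick H. Lower were dre-miR-737-5p, mdo-miR-128a-5p, oha-miR-9-4-5p and ssa-miR-301a-5p, the last between -0.62 in slick M, where it was not called, and -1.79 in source M. The far more abundant aca-miR-9-5p, of the same family number as oha-miR-9-4-5p, lay between -0.09 in source L and -0.42 in slick L. It was called lower in slick L and source H only. In all 3 slick doses oar-miR-23b, dre-miR-23a-3-5p and oan-miR-458-5p rose and mdo-miR-128a-5p and oha-miR-9-4-5p fell. Over all names past the filter 59 were called at least once and 0 in at least 4 exposures.

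**Figure D3:**
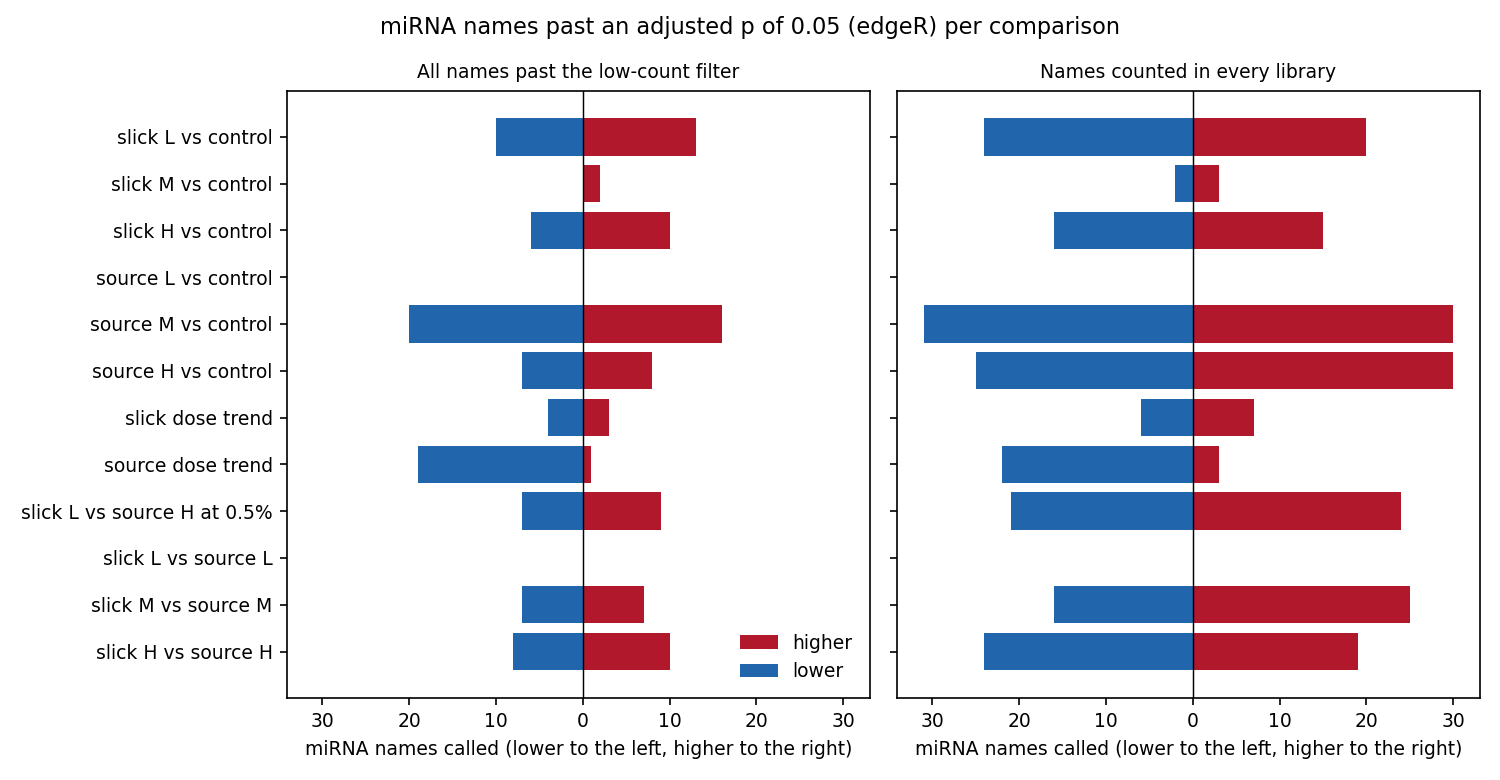
Bars give the number of miRNA names called at an adjusted p of 0.05 in each comparison, lower to the left and higher to the right, over all names past the filter (left panel) and over names counted in every library (right panel). Source L gave 0 calls in both panels, and source M gave 36 in the left panel and 61 in the right.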

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

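In this part the tests chosen only after the result was seen were those over names counted in every library, the count of libraries outside the set of 7, the position of library L3, the family test over the 6 tables together and the count without library M5. Among names counted in every library, 9 were called one way in at least 1 slick exposure and the other way in at least 1 source exposure. Of these, 4 did so between slick L or slick H and source H, groups that were also compared directly. All 3 source H libraries belonged to the set of 7 that stood apart on the first component. These comparisons therefore cannot tell the oil from a batch shared by that set. Slick H (2%) and source H (0.5%) also differed in nominal concentration, so oil and dose cannot be told apart between them. The name sha-miR-92a lay 3.35 (log2) higher in slick L than in source H, at 1.36 and -1.72 against control. Against the same group ssa-miR-7132b-5p lay at -1.46 in slick L (-0.76 and 1.0 against control) and ssc-let-7i at -1.06 (-0.53 and 0.83). In slick H against source H ola-miR-731 lay at -1.56 (-0.89 and 0.80 against control), sha-miR-92a at 3.05 (1.19 and -1.72) and ssa-miR-7132b-5p at -1.86 (-1.0 and 1.0). In each of these direct comparisons the 3 libraries of one oil lay on one side of the 3 of the other. Over all names past the filter, 16 names differed between slick L and source H, 14 between slick M and source M, and 18 between slick H and source H. The 3 source M libraries belonged to the set of 7 as well. No test for single libraries far from the rest was run within the groups of 3.

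Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. The real split called 23 names in slick L (highest other split 3), 2 in slick M (4), 16 in slick H (3), 0 in source L (5), 36 in source M (2) and 15 in source H (4). In slick M 4 of the 10 splits gave at least as many calls as the real one, in source L all 10 did, and in the other exposures 1 did, the real one. Over names counted in every library the real counts were 44, 5, 31, 0, 61 and 55, and the highest other counts 0, 1, 0, 0, 1 and 0. The direct comparisons called 16 names between slick L and source H (highest other split 5), 0 between slick L and source L (4), 14 between slick M and source M (1) and 18 between slick H and source H (2). For names counted in every library these were 45, 0, 41 and 43, with 0 as the highest other count in each. The list tests called 0 lists in each exposure in the real split, and the highest other count was 1 in slick H and source H and 0 in the other exposures, so all 10 splits gave as many.

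For the dose trends 100 splits were drawn. In the slick dose trend 4 of them gave at least the 7 calls of the real split, and 4 gave at least the 13 among names counted in every library. In the source dose trend 2 gave at least the 20 calls of the real split, and 2 gave at least the 25. Each share, the real split included, lies under 0.05, but it rests on 100 splits and was not adjusted over the trends tested, so chance is not firmly excluded. The splits mix control and exposed libraries and so do not test a slope among the doses alone. With the control libraries left out, edgeR called 0 names in each trend. The highest other splits called 30 and 34 names for slick oil and 22 and 37 for source oil, and for slick oil such a count, several times the real one, points to a structure of the samples, whose nature was not tested.

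The 3 source M libraries, the 3 source H libraries and library L3 of source L stood apart from the other 14 on the first component. Depth was argued against, since 7 of the 7 still lay beyond the others when each library was thinned to the lowest total, at 5.08 or above against at most -1.82. On a line from the control mean (0) to the mean of source M and H (1), L3 lay at 1.01 and L1 and L2 at 0.18 and 0.11, which puts L3 0.86 above their mean. The labelled dose, which L3 shares with L1 and L2, thus does not by itself account for its place. This position restates the first component, on which L3 had been picked out, so it is not a separate test of dose. A wrong label on L3 may account for its place, since its mean distance was 6.76 to the 6 source M and H libraries, which lay 6.91 to 9.24 from one another, and 11.42 to L1 and L2, and a batch shared by all 7 would place it there too. For source M and source H, a batch shared by the 7 and the response to source oil cannot be told apart, because 0 libraries of these groups lay outside the set.

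In all, 91 names held 0 in 1 control library beside at least 100 counts in another. Sampling of rare miRNAs was argued against, since 72.5% of these names reached 1000 counts or more in a control library, with a median of 7204. A candidate explanation is that reads of 1 family went to different names in different libraries. Within single tables Fisher's exact test of family membership passed in 0 of 6, and it could not decide, because each table lists only names found in its first exposed library and can lack the partner name, while over the 6 tables together 81 of the 91 names had a partner of their family with the opposite zeros, against a mean of 34.6 (18 to 53) in 1000 shuffles of the families (permutation p = 0.001, the smallest these can give). No biological explanation was tested, since these zeros separate libraries of the same control group.

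Slick M gave 2 calls, and 5 among names counted in every library, beside 44 and 31 for slick L and slick H in that set. Spread in library M5 may account for part of this, since without M5 32 of the names counted in every library were called, although over all names the count went to 0. Smaller changes at 1% stay open as the biological explanation. Of the 27 names called the same way in slick L and slick H, 22 had a smaller fold change in slick M without M5 than in both (medians 0.68, 1.06 and 1.25), but names picked for their calls in the other groups lean that way by selection, and the count fell between the bounds set beforehand. Slick M was not tested directly against slick L or slick H.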

How the results depend on the processing

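In this part the alternatives chosen only after seeing the data were those over names counted in every library, with or without merged names, dose as a rank or single libraries left out. No paired analysis was possible because the count columns carry numbers that do not follow the replicate numbers of the titles, so the planned block on the replicate number was not run. Of the alternative values of the counts of calls, 165 stayed within 1.5 times the first value and 138 moved further. Of 2799 alternative values of the 162 named miRNA values, 1975 kept their direction and side of the threshold, 334 passed it anew, 490 no longer passed and 0 reversed. The number of calls over all names changed widely when single libraries were left out, as the ranges below show. The 3157670 to 8736995 counts per exposed library did not remove the zeros beside high counts. For each value below the cause was not tested, except that leaving out libraries or the control group lowers the number of samples and that a minimum fold change can only lower a count.

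With DESeq2 the count of calls was 57 for slick L vs control, 24 for slick M vs control, 45 for slick H vs control, 32 for source L vs control, 77 for source M vs control and 68 for source H vs control. It was 16 for the slick dose trend, 37 for the source dose trend, 56 for slick L vs source H at 0.5%, 17 for slick L vs source L, 46 for slick M vs source M, 46 for slick H vs source H and 15 for the slick H and source H overlap. With 1 fit over all 21 libraries it was 6 for slick L vs control, 0 for slick M vs control, 4 for source L vs control, 47 for source H vs control, 46 for slick L vs source H at 0.5%, 1 for slick L vs source L, 41 for slick M vs source M, 44 for slick H vs source H and 6 for the slick H and source H overlap.

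Over the names counted in every library the count was 44 for slick L vs control, 5 for slick M vs control, 31 for slick H vs control, 61 for source M vs control, 55 for source H vs control, 13 for the slick dose trend, 45 for slick L vs source H at 0.5%, 41 for slick M vs source M, 43 for slick H vs source H and 8 for the slick H and source H overlap (9 when both exposures were fitted over the names counted in all 9 libraries). With names sharing reads merged as well, it was 43 for slick L vs control, 4 for slick M vs control, 32 for slick H vs control, 56 for source M vs control and 48 for source H vs control. In the same set the slick dose trend gave 11 with dose as a rank, and the source dose trend gave 38 without source L library L3.

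With total counts only as scaling, over all names, the count was 7 for source M vs control, 30 for source H vs control, 12 for the source dose trend, 32 for slick L vs source H at 0.5%, 0 for slick M vs source M and 2 for the slick H and source H overlap. With RLE size factors it was 29 for source H vs control, 28 for slick L vs source H at 0.5% and 2 for the slick H and source H overlap. With no filter it was 14 for slick L vs control and 8 for slick M vs source M, and with a minimum absolute log2 fold change of 1 it was 15 for slick L vs control. Dose as a rank gave 33 for the source dose trend, and exposed groups only gave 0 for the slick dose trend and 0 for the source dose trend.

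Leaving out 1 library at a time gave 9 (without C6) to 21 (without L4) for slick L vs control, 0 (without M5) to 8 (without M4) for slick M vs control, 1 (without C5) to 22 (without H4) for slick H vs control, 0 to 2 (without C5) for source L vs control, 11 (without C6) to 50 (without M5) for source M vs control and 0 (without H2) to 36 (without H3) for source H vs control. It gave 0 (without C4) to 11 (without slick L library L5) for the slick dose trend, 0 (without C6) to 30 (without source L library L3) for the source dose trend, 0 (without slick L library L5) to 39 (without source H library H3) for slick L vs source H at 0.5%, 0 to 1 (without source L library L1) for slick L vs source L, 0 (without slick M library M4) to 13 (without source M library M5) for slick M vs source M, 0 (without source H library H2) to 30 (without source H library H3) for slick H vs source H and 0 to 4 (without source H library H3) for the slick H and source H overlap. With names counted in every library it gave 25 (without L5) to 45 (without C5) for slick L vs control, 0 (without C4) to 32 (without M5) for slick M vs control, 19 (without C6) to 36 (without H4) for slick H vs control, 0 to 27 (without L3) for source L vs control, 40 (without C4) to 69 (without M5) for source M vs control and 12 (without C6) to 59 (without H3) for source H vs control.

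For the lists fry gave 2 calls in the slick M miRNA list tests (endothelial and smooth muscle, adjusted p = 0.000789, and epithelial, 0.00821), 2 in the slick H miRNA list tests (Hox cluster, and liver, gut and pancreas, both 0.00845), 1 in the source M miRNA list tests (epithelial, 0.00794) and 1 in the source H miRNA list tests (endothelial and smooth muscle, 0.03), each toward higher levels, where camera gave 0. Fry tests a list against no change and camera against the other names, so these calls do not set a list apart from other miRNAs. Leaving out 1 library gave 0 to 1 list with camera in the slick M miRNA list tests (without C5) and 0 to 1 in the source L miRNA list tests (without L3).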

Other observations

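The fits of source L without library L3 were chosen only after the result was seen, and so were the names singled out in the paragraph that follows. In source L without L3, 27 of the names counted in every library were called, 11 higher and 16 lower. The endothelial family names oar-miR-23b (log2 fold change 1.33 ± 0.22), dre-miR-23a-3-5p (1.17 ± 0.21) and tgu-miR-126-5p (1.2 ± 0.24) were higher, as were the teleost miRNA ola-miR-462 (0.97 ± 0.20) and the muscle miRNA ssa-miR-206-5p (0.94 ± 0.20). The red blood cell miRNA ssa-miR-144-3p (-0.97 ± 0.16), the white blood cell miRNA ola-miR-142 (-1.18 ± 0.28), ola-miR-101b-3p (-1.57 ± 0.25) and ola-miR-148 (-1.04 ± 0.21) were lower. These calls shared 6 higher and 9 lower names with slick L and 4 and 6 with slick H, with 0 in opposite directions in either. With source M they shared 5 higher and 3 lower names and 8 went in opposite directions, and with source H 6 and 3 and 3 did. All of these comparisons used the same 3 controls, and shared controls were not simulated for them. The names ola-miR-142 and tgu-miR-142-5p have the same counts, and ola-miR-19b and ssa-miR-19c-4-5p nearly the same. Both pairs are among the 8 names opposite to source M. The miR-142 pair is also among the lower names shared with slick L and slick H, so these names are not all separate cases.

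Some families not described above were called in the names counted in every library. The names ola-miR-100 (0.85 in source M and 1.33 in source H) and chi-miR-125b-5p (1.17 and 1.33), of families encoded beside let-7 genes in vertebrates, rose in both exposures, and chi-miR-125b-5p rose by 0.64 in slick L. Of families encoded beside miR-23 genes, mdo-miR-24-3p (0.54 and 0.89) rose and efu-miR-27b (-1.18 and -1.33) fell. The sensory organ miRNA chi-miR-182 fell from 15981 ± 2370 to 7954 ± 2263 CPM in source M and from 13737 ± 2035 to 7499 ± 2617 CPM in source H (-1.01 ± 0.26 and -0.87 ± 0.31), while chi-miR-96, of the same cluster, lay at 0.53 ± 0.22 and 0.62 ± 0.31 and was not called. The gut family name ssa-miR-194b-5p, at 14.9 ± 2.43 CPM in control beside source M, fell in slick L (-0.87), source M (-1.47) and source H (-1.24). The more abundant ola-miR-194-5p of the same family stood at 106 ± 5.2 CPM in control and 103 ± 17.5 CPM in source M and was not called there. The epithelial name sha-miR-200a fell in slick L (-0.75) and slick H (-0.87). Over all names past the filter, scaling by total counts moved the medians of source M and source H by -0.22 and -0.42. These shifts are smaller in size than each called log2 fold change given here for these exposures. That does not show that the calls hold, since this scaling left 7 of 36 as the count of calls in source M over all names. It was not run over the names counted in every library.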
